A study of Mus musculus with 2 samples.

How the data were processed

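Cells positive for VE-cadherin, CD61 and EPCR had been sorted from dissected C57BL/6 mouse embryos and made into 2 single-cell RNA libraries with the 10x Genomics version 2 chemistry for transcript 3' ends, sequenced on an Illumina NextSeq 500, per the labels' protocols. The deposited values were UMI counts per gene and cell, in 1 matrix of 27998 genes for each library. The submitters' processing notes list Cell Ranger 2.1.1 and the mm10 genome; alignment settings and the rule by which barcodes were called cells are not given in the sources used here. The matrices held whole numbers only, and no barcode had fewer than 5622 counts, so empty barcodes had been removed before deposit. No annotation of cells was used here.

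Cells with at least 1000 genes and at most 10% of counts on mitochondrial genes were kept, which removed 1 of 543 cells at E9 and 5 of 1298 at E9.5, all by the mitochondrial limit. Kept cells had 7036 to 125369 UMIs at E9 and 5622 to 99194 at E9.5. Scrublet was run on each library and called 4 cells at either stage (0.738% and 0.309%); they were kept, and leaving them out was tried. For 56 symbols given to more than 1 gene identifier, no value was used in the gene lists.

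Both libraries were clustered together without correction for library (counts scaled per cell and log transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.6). A cluster was called X-like from marker sets fixed before the data were examined; the way markers were scored, the share of a set at least 2-fold above the other cells together with the markers among the 10 leading genes, was settled after the data were seen. Cluster 8, named after epithelial and neural markers, was left out of the cells called endothelial and haematopoietic. When another cell filter was tried, cells kept the names of their first cluster, a choice made after seeing the data; new clusters were tried as well.

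Counts were summed over the cells of a group and given as CPM, a scaling to the same summed total in every group, with exact Poisson intervals. The ratio of 2 sums has an exact conditional binomial interval at 95%. With 1 library per stage no test across samples exists, and cells were not used as replicates. A gene at 0 in a group was set at a floor of 3 counts, which gives a bound, and no ratio was given where both groups were at or under that floor. Positions are 1-based and come from the GENCODE M21 annotation, whose identifiers matched 27645 of the 27998 genes (98.74%). Gene lists were fixed before the data were examined. A list's median was taken over members with a pooled CPM of 5 or more and set among 10000 random lists of the same size matched in 20 bins of expression; a member was called higher or lower at a ratio of 1.5 or more. The intervals of list medians come from 200 Poisson draws of the counts, and members at 0 counts enter at their bound. A member whose bound lies past a ratio of 1 enters at a log2 ratio of 0. A list median of exactly 0 can then stand for members too low to measure.

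A cell was called positive for Runx1 or Cxcr4 with at least 1 UMI after thinning to 9000 UMIs, the 5th percentile of UMIs over kept cells rounded down to a multiple of 500. This left 528 cells of E9 and 1216 of E9.5, cluster 8 included. Shares have exact Clopper-Pearson intervals, and a share of 0 is given with the limit of 3 cells. Ratios between positive and negative cells use the full counts of these cells. On unthinned counts a cell was called positive with at least 1 UMI, and a split needed 5 cells on each side. The share of endothelial RNA in cluster 8 was read from pan-endothelium genes of at least 20 CPM in endothelial cells, Sox18 left out. Since thinning is random, 100 further draws were made after seeing the data and their range is given where it matters.

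The rule for named genes was fixed before the data were examined. Among genes with 20 CPM or more in the higher group and a UMI in at least 5% of its cells, leaving out mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, unnamed gene models and the gene defining the split, the 12 higher and the 12 lower genes with the interval bound farthest from a ratio of 1 were named. For splits made in both libraries the direction had to be the same in both, ranked by the library whose bound was nearer to 1. Up to 4 members of each list with the largest ratios were eligible besides, and a fixed set of genes, Runx1 and Cxcr4 among them, was always eligible. Not every eligible gene is printed. The cluster markers are given as markers and not as results.

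The alternatives covered the cell filter, doublets, 3 other scalings, equal weights for cells, the gene floor, the cells compared, the thinning number, the UMI minimum, clusters in place of Runx1-positive cells, the clustering and members shared between lists. Added after seeing the data were removal of the trend with the GC content of the last 400 bases of transcripts, genes with under 10% of the 50-base words of these ends in another gene, removal of cells with over 5% haemoglobin counts or with 3 or more macrophage or platelet UMIs, new clusters under other cell filters, and the further thinning draws. The median log2 ratio of all genes fell by at most 0.077 under any scaling or the GC correction.

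The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. The ratio intervals were tested on simulated data for E9.5 against E9 over all kept cells. The simulated sums were Poisson counts, the model that the intervals assume. This checks the computation and not the spread between real cells, and the splits with fewer cells were not simulated. Of 9018 unchanged genes 94.2% of intervals held the true ratio, and of 50 genes at each of 1.5-fold, 2-fold, 4-fold and 8-fold 92%, 90%, 98% and 96% did, with all intervals on the right side of 1. A simulated list raised 2-fold stood at the 100th percentile with a median of 0.98, and an unchanged list at the 23.1st. In simulated cells with 1 true level at both stages, shares of 30.6% and 23.1% became 12.9% and 10.9% after thinning, where 11.8% was expected.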

Results

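The study sorted cells carrying VE-cadherin, CD61 and EPCR from a trunk region of mouse embryos in which definitive blood cells form. Both libraries came from the para-aortic splanchnopleura, the forerunner of the aorta-gonad-mesonephros region. VE-cadherin is an adhesion protein of endothelium, and CD61 and EPCR mark its hemogenic part, the endothelium that gives rise to blood cells. The series holds 2 single-cell libraries, 1 from embryonic day 9 (E9) and 1 from embryonic day 9.5 (E9.5), and no replicate of either stage. The E9 library held 543 barcodes with 18674104 counts, and the E9.5 library held 1298 barcodes with 32260947 counts. After filtering, 542 and 1293 cells were kept, with a median of 32208 UMIs and 5541.5 genes per cell at E9 and 22453 UMIs and 4844 genes at E9.5. Each stage is 1 library, so a difference between stages is a difference between these libraries, and no p-value was computed. Intervals of levels, shares and gene ratios are exact 95% Poisson, binomial or conditional binomial intervals, and those of list medians come from 200 simulated Poisson draws. Both kinds cover counting error only. A list percentile is the place of the list's median among 10000 random lists matched on size and expression, and describes these libraries.

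The transcripts of the sorted proteins were present at both stages. Cdh5, which encodes VE-cadherin, stood at 440.1 CPM at E9 and 457 CPM at E9.5 and had a UMI in 90.8% and 93.1% of cells. Procr, which encodes EPCR, stood at 27.3 CPM and 36.4 CPM. Itgb3, which encodes CD61, was low, at 2.36 CPM and 5.71 CPM, with a UMI in 7.01% and 8.51% of cells.

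The cells fell into 10 clusters, most of which came almost entirely from 1 library. Cluster 4 took the name hemogenic-endothelium-like, by a scoring of markers settled after the data were seen, but was mixed, led by Rac2, Lyz2, Plek, Myb, Tyrobp, Prtn3, Pf4, Gfi1 and Spi1, so that blood progenitor, macrophage and platelet genes stood beside the hemogenic markers among its leading genes. It held 8 cells of E9 (1.48%, 0.639% to 2.89%) and 180 of E9.5 (13.9%, 12.1% to 15.9%). In this cluster 13 of 14 hemogenic, 15 of 15 hematopoietic progenitor, 12 of 12 macrophage and 8 of 10 megakaryocyte markers were at least 2-fold above the other cells. Its name rests on the 3 hemogenic markers among its 10 leading genes. Cluster 2, with 243 cells of E9.5, was arterial-endothelium-like with Bmx and Hey2, and its Gja5 level was 679 CPM. Cluster 1, with 363 cells of E9.5, was venous-endothelium-like with Nr2f2, Aplnr and Nrp2, and its Gja5 level was 4.09 CPM. Cluster 10, with 17 cells of E9, was venous-endothelium-like with Lyve1, Stab2 and Mrc1. Clusters 6, 7 and 9 held 148, 160 and 145 cells of E9 and met no marker set. Cluster 6 was led by the haemoglobin genes Hbb-bh1 and Hbb-y, followed by Etv2, a regulator of early endothelium, at 23.0 CPM. It also held 17 cells of E9.5, with a median of 7194 UMIs. Over all kept cells Hbb-bh1 had 30 counts at E9 and 7636 at E9.5. Runx1 stood at 36.8 CPM in cluster 7 and Gja5 at 388.7 CPM in cluster 9. Clusters 3 and 5, with 218 and 176 cells of E9.5, also stayed unnamed and were led by Cav1 and Clec1a and by Foxf2 and Stra6. Cluster 8 was epithelial-like and neural-like with Pax3, Cldn6 and Tfap2b, also carried 11 of 14 mesenchymal markers, and held 11.3% of E9 cells (8.72% to 14.2%) and 6.81% of E9.5 cells (5.49% to 8.32%). Cdh5 stood at 16.1 CPM and 22.1 CPM in cluster 8. A cluster made mostly of 1 library may be that library and not a cell type, so cluster sizes are given and not compared. All clusters but cluster 8 are called endothelial and haematopoietic cells below.

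The comparison of E9.5 with E9 over all kept cells shows how the sorted population differed between the stages. RNA of hemogenic endothelium and blood progenitors was higher at E9.5, RNA of glycolytic enzymes was lower, and arterial and cell cycle genes differed little on the median. The median log2 ratio of the hemogenic endothelium list was 0.71 (0.50 to 0.88; 100th percentile), with 6 of 11 measured members at least 1.5-fold higher and 1 at least 1.5-fold lower. Gfi1, a repressor needed as blood cells leave the endothelium, stood at 10.1 CPM at E9.5 and 2.89 CPM at E9 (log2 1.81, 1.39 to 2.25). Spi1, a regulator of blood lineages, stood at 24.2 CPM and 8.95 CPM (1.43), and Neurl3 at 8.26 CPM and 2.68 CPM (1.62). Itga2b, an early blood marker, went the other way, at 5.99 CPM and 20.7 CPM (-1.79). Runx1, the regulator of the endothelial-to-hematopoietic transition (ENSMUSG00000022952, mm10 chromosome 16, 92601466 to 92826149), stood at 17.9 CPM and 14.4 CPM (0.32, 0.10 to 0.53). The blood progenitor list had a median of 0.66 (99.95th percentile), with 3 of 5 measured members higher; Fcer1g stood at 13.4 CPM and 4.82 CPM and Coro1a at 24.9 CPM and 15.3 CPM. Both medians rest partly on genes of low level: with a floor of 20 CPM per gene they were 0.18 and 0.33. Macrophage and haemoglobin RNA was higher at E9.5 along with them: Lyz2 stood at 8.19 CPM and 0.589 CPM, the macrophage list at 2.24 over 2 measured members (0.89 with no floor on genes), and the haemoglobin list at 6.54. Haemoglobin genes took 0.0848% of counts at E9.5 and 0.00141% at E9, with Hba-x at 128 CPM and 0.643 CPM and Hbb-bh1 at 237 CPM and 1.61 CPM. Without the 3 E9.5 cells that held over 5% haemoglobin counts the haemoglobin median was 2.44.

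Among endothelial genes, the transcription factor gene Sox18 (ENSMUSG00000046470, mm10 chromosome 2, 181669836 to 181671640) stood far lower at E9.5, at 16.5 CPM against 294.6 CPM (log2 -4.16, -4.29 to -4.03). Lyve1 stood at 8.85 CPM and 58.9 CPM (-2.73), and Stab2 at 2.98 CPM and 14.9 CPM (-2.33). Both encode hyaluronan receptors of venous, sinusoidal and lymphatic endothelium, and both led cluster 10, which held 17 cells of E9 and 0 of E9.5. Gpr182 (-2.17), Plaur (-1.89) and Etv2 (-1.44) were lower as well, while Nr2f2, a regulator of venous identity, was higher (0.69). The venous and early endothelium list had a median of -0.19 (1.21st percentile), which was 0.23 with a floor of 20 CPM, and the pan-endothelium list had -0.018 with Tie1 at -0.70. The arterial endothelium list stood at 0.051 (51.4th percentile), with Bmx at 1.73 and Jag1 at 0.62. Dll4 (-0.24), Gja5 (-0.17), Efnb2 (-0.017) and Mecom (-0.085) differed by less than 1.5-fold. The chemokine receptor gene Cxcr4 (ENSMUSG00000045382, mm10 chromosome 1, 128588199 to 128592293) stood at 1.12 CPM at E9.5 and 6.80 CPM at E9 (-2.61, -3.18 to -2.06). The Notch pathway list had a median of 0.22, the VEGF and shear response list 0.15, the BMP and TGF-beta response list 0.14, and the extracellular matrix and adhesion list -0.025. Within these, Adm stood at -1.19 and the basement membrane gene Col4a1 at -1.12.

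Glycolysis genes had a median log2 ratio of -0.46 (-0.49 to -0.44; 0th percentile), with 4 of 15 members at least 1.5-fold lower and 1 higher. The median was -0.43 in endothelial and haematopoietic cells alone and -0.57 (-0.65 to -0.51; 5 of 13 lower) in cluster 8, so the lower level was shared by both. The lactate exporter gene Slc16a3 stood at 59.2 CPM and 166.2 CPM (-1.49), Hk2 at 5.06 CPM and 13.7 CPM (-1.43), and Pgk1 went the other way, at 134.4 CPM and 57.2 CPM (1.23). Gapdh stood at 343 CPM and 1823 CPM (-2.41), but 87.7% of its transcript end is shared with other genes of the annotation, so its value is uncertain. The hypoxia response list had a median of -0.23 (0.820th percentile). The Wnt response list had a median of 0.70 (99.9th percentile), with 3 of 5 measured members higher: Tcf7 at 1.84, Nkd1 at 0.94 and Lef1 at 0.70. Cell cycle lists lay near 0, at 0.0076 for G1/S and 0.024 for G2/M, and cell cycle inhibitors had a median of 0.26. The stem cell associated list had a median of -0.085 (6.57th percentile), although Hlf, a gene of blood stem cells, stood at 3.38 CPM and 1.13 CPM (1.59, 0.91 to 2.34). Kit (-0.035), Cdkn1c (-0.12) and Cdh5 (0.056) were close to equal, Itgb3 (1.28) was higher at E9.5, and Procr (0.41) differed by less than 1.5-fold. Ptprc, the pan-leukocyte gene, stood at 0.993 CPM and 0.214 CPM. Of lists of other tissues, epithelium stood at -1.09 over 2 measured members, with Krt8 at -1.68, and mesenchyme at -0.33 with Meox1 at -1.56. The neural list stood at -0.10, but at 0.46 with cells weighted equally. Within cluster 8, where more members were measured, epithelium stood at -0.78, neural at 0.65 (99.97th percentile) and mesenchyme at 0.046, so the lower mesenchyme median was not seen there.

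The genes with the largest differences by the fixed rule belonged to no single list. Cebpb, which encodes a transcription factor of myeloid cells (ENSMUSG00000056501, mm10 chromosome 2, 167688915 to 167690418), stood at 41.9 CPM at E9.5 and 0.268 CPM at E9 (log2 7.29, 6.06 to 8.91). Eid2 stood at 33.6 CPM and 2.52 CPM (3.74), Crls1, an enzyme of cardiolipin synthesis, at 39.9 CPM and 5.73 CPM (2.80), and Basp1 at 250.1 CPM and 52.5 CPM (2.25). Ccdc71l (2.74), H1fx (2.11), Ramp3 (2.1), Tbx1 (2.02), Akirin2 (1.99), Plekha3 (1.96), Ppp1r14b (2.16) and the histone gene Hist1h2ap (2.60) were also higher. Besides Sox18, Lyve1, Gapdh, Gpr182 and Plaur, the lower genes were Spag7 (-2.08), Nptn (-1.96), Igfbp5 (-1.95), Tuba1c (-1.92), Inpp5a (-1.84), Pigt (-1.82) and AY036118 (-2.70). Hist1h2ap and AY036118 share 100% of their transcript ends with other genes, Tuba1c 59.3% and Ppp1r14b 11.1%, and their values are uncertain. Cluster 8 also held some endothelial RNA, with Cdh5 at 3.33% and 4.60% of its endothelial level and no pan-endothelial gene over 15.1%. Of these 24 genes, 17 stood in cluster 8 at over 2 times the highest such share, at the stage with more. All 17 pointed the same way there: Eid2 stood at 4.02, Basp1 at 2.48 and Gapdh at -2.43, while Igfbp5 stood at -0.34. Genes that changed in cluster 8 as well pass this limit more easily, so their shared direction does not speak for all 24. The other 7 genes, Sox18, Lyve1, Gpr182, Plaur, Cebpb, Ramp3 and Tbx1, did not pass this limit. Plaur (16.8%), Cebpb (25.4%), Tbx1 (27.9%) and Ramp3 (29.1%) stood above the highest pan-endothelial share of their stage, but by less than 2 times. Sox18, Lyve1 and Gpr182 stood below it.

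**Figure D1:**
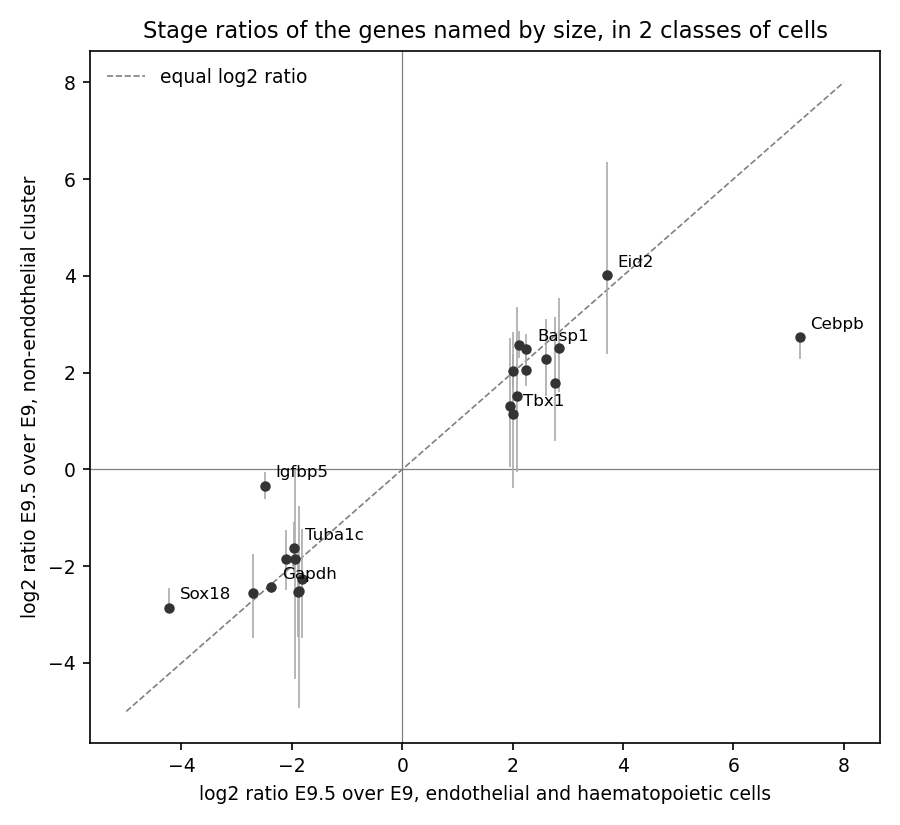
Log2 ratio of E9.5 over E9 in endothelial and haematopoietic cells (horizontal axis) and in non-endothelial cluster 8 (vertical axis) for the 22 of 24 genes with counts in both. Vertical lines are 95% counting intervals, the dashed line marks equal ratios, and Sox18 and Cebpb are drawn at their bounds in cluster 8. Sox18, Cebpb, Plaur, Ramp3 and Tbx1 stood there within 2 times the highest share of a pan-endothelial gene. Eid2, at 3.70 and 4.02, and Gapdh, at -2.37 and -2.43, lie near the line, and Igfbp5, at -2.49 and -0.34, lies off it.

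Runx1-positive cells were counted to measure the hemogenic share at each stage. With every cell thinned to 9000 UMIs, 37 of 471 endothelial and haematopoietic cells had a Runx1 UMI at E9 (7.86%, 5.59% to 10.7%) and 130 of 1143 at E9.5 (11.4%, 9.59% to 13.4%), so the intervals overlapped. In cluster 8, used as the background, 0 of 57 cells had one at E9, which allows a share of up to 5.26%, and 2 of 73 at E9.5 (2.74%). Without thinning the shares were 13.7% and 15.9%, against 6.56% and 3.41% in cluster 8. Cells with fewer than 9000 UMIs were left out, so thinning kept 471 of 481 endothelial and haematopoietic cells at E9 and 1143 of 1205 at E9.5. The Runx1-positive cells lay in different clusters at the stages: at E9, 28 of 37 (75.7%) lay in cluster 7 and 5 (13.5%) in cluster 4, while at E9.5, 109 of 130 (83.8%) lay in cluster 4. Cluster 7 held 157 thinned cells of E9 and 4 of E9.5, and cluster 4 held 8 and 175. This split thus largely follows the libraries and says little about the stages. Within cluster 4, 5 of 8 cells were positive at E9 and 109 of 175 at E9.5. The share of Runx1-positive cells at E9.5 depends on cluster names: in a repeat with the cells clustered again after a stricter cell filter, cluster 4 was also named macrophage and left out, and 2.46% of the cells left were Runx1-positive, against 11.4%.

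**Figure D2:**
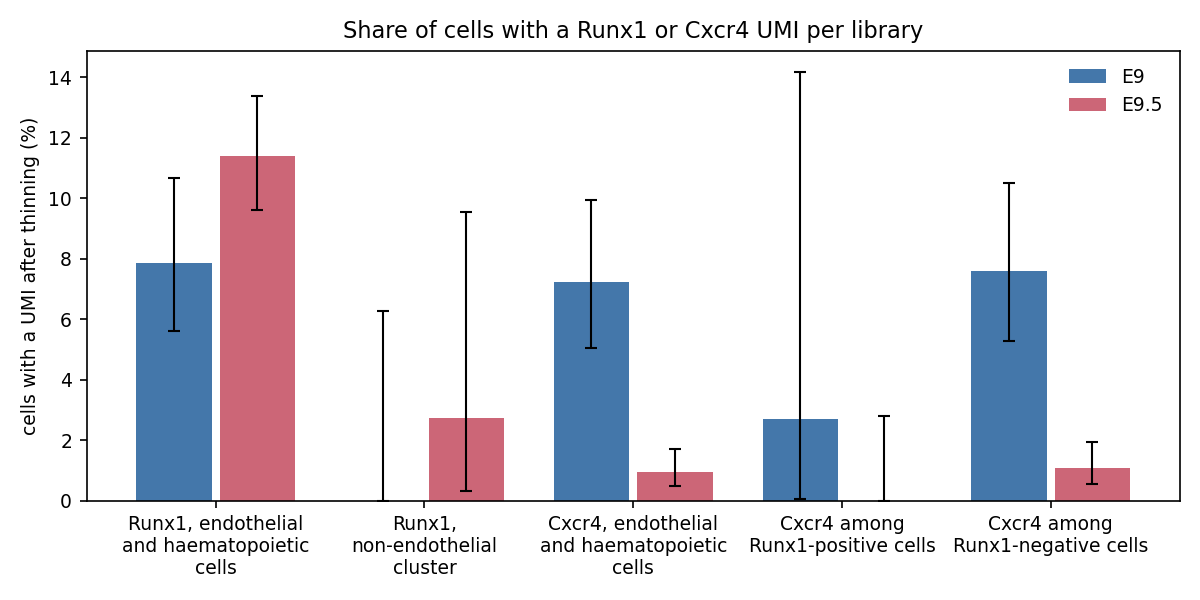
Percent of cells with a Runx1 or Cxcr4 UMI after thinning to 9000 UMIs, per library; bars are shares and error bars exact 95% binomial intervals. Runx1 stood at 7.86% and 11.4% of endothelial and haematopoietic cells at E9 and E9.5, and Cxcr4 at 7.22% and 0.962%.

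Runx1-positive cells were compared with Runx1-negative cells within each library to describe hemogenic cells against the other endothelium. At both stages Runx1-positive cells carried more RNA of hemogenic and blood progenitor genes and of stem cell associated genes, and less of venous and Wnt response genes. They also carried less of pan-endothelial genes, which at E9.5 depended on cluster 4. The hemogenic endothelium list had a median log2 ratio of 1.63 at E9 (1.32 to 1.90; 6 of 8 members higher) and 2.90 at E9.5 (2.70 to 3.06; 10 of 10 higher). Gfi1 stood at 20.3 CPM in positive and 1.62 CPM in negative cells at E9 (3.65) and at 73.6 CPM and 3.62 CPM at E9.5 (4.35). Spi1 stood at 70.5 CPM and 4.48 CPM at E9 (3.98) and at 171.3 CPM and 8.83 CPM at E9.5 (4.28). Ikzf2 (3.27 at E9 and 3.42 at E9.5), Adgrg1 (2.08 and 3.69) and Bcl11a (1.65 and 2.37) were higher at both. The blood progenitor list had medians of 1.98 and 2.84, with Coro1a at 1.98 and 3.21, Alox5ap at 2.30 and 2.60 and Cd44 at 0.66 and 1.86. Without cells that held macrophage or platelet RNA these medians were 1.33 and 1.85. Fcer1g stood at 3.03 and 2.84, but only 10.8% of the positive cells at E9 had a UMI, and over 100 further thinning draws its E9 value ran from -3.12 to 4.89. Ptprc had 2 counts in either group at E9 and stood at 6.49 CPM against 0.443 CPM at E9.5. Macrophage genes were higher in the positive cells of E9.5 as well, with a list median of 3.59 and Fcgr3 at 3.53; at E9 Fcgr3 alone was measured, at 0.80 (-0.21 to 1.69).

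The stem cell associated list had medians of 0.52 at E9 (0.39 to 0.67; 7 of 16 members higher, 0 lower) and 0.55 at E9.5 (0.42 to 0.70; 8 of 17 higher, 0 lower), both at the 100th percentile. With cluster 4 in place of Runx1-positive cells the medians were 0.29 (-0.0052 to 0.47) and 0.70 (0.51 to 0.76). Hlf stood at 2.49 and 3.90, Meis1 at 1.51 and 2.05, Hoxa9 at 2.22 and 1.85 and Hoxa7 at 1.90 and 0.98. The trunk Hox list had medians of 0.51 and 0.21, with Hoxa5 at 0.84 and 0.74, but -0.36 and -0.0011 with cluster 4 in place of Runx1-positive cells. Kit, the stem cell factor receptor, stood at 0.96 and 1.79, Procr at 1.24 and 1.36 and Itgb3 at 1.12 and 3.09. Outside the lists, Nupr1, a stress-response gene, stood at 111.2 CPM against 6.03 CPM at E9 (4.20) and 130.7 CPM against 5.99 CPM at E9.5 (4.45). The Wnt modulator gene Sfrp2 (3.10 and 3.79), Ifitm1 (2.81 and 2.77), the keratin gene Krt18 (2.52 and 3.18), the phosphatase gene Ptpn6 (2.37 and 2.95) and Gsn (2.72 and 2.50) were higher at both stages, although Gsn at E9 reached -0.28 in a further draw. Dlk1 stood at 2.70 and 1.44.

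Venous and early endothelium genes were lower in Runx1-positive cells, with medians of -1.36 (9 of 12 members lower) and -1.31 (5 of 9 lower, 1 higher). Aplnr stood at -1.94 and -2.68, Nr2f2 at -1.77 and -2.57, and Nrp2 at -1.29 and -2.14. The pan-endothelium list had medians of -0.41 and -0.54, with the VEGF receptor gene Kdr at -1.12 and -1.58, Eng at -1.10 and -0.83, Emcn at -0.85 and -0.90, and Cd34 at -0.70 and -0.74, while Cdh5 stood at -0.15 and -0.28. VEGF and shear response genes had medians of -0.57 and -1.0, with the apelin gene Apln at -5.44 and -3.26 and Esm1 at -4.00 and -2.14. Wnt response genes had medians of -1.26 and -2.56, with all 4 measured members lower at E9 and 4 of 5 at E9.5: Ccnd1 at -2.68 and -2.56, Lef1 at -1.44 and -2.70, and Nkd1 at -1.09 and -3.68. The Wnt receptor gene Fzd10 stood at -5.04 with 1 count in the positive cells of E9 (-10.35 to -2.55) and -3.51 at E9.5. Kcne3 (-4.14 and -3.16), Tmem255a (-3.05 and -2.50), Apold1 (-3.06 and -2.21), Sgk1 (-2.73 and -2.50), Slc39a8 (-2.73 and -2.52) and Clec1b (-2.49 and -2.50) were lower at both stages. Vwa1 and Pde2a, with 17.7% and 100% of their transcript ends shared, stood at -3.34 and -4.33 and at -2.49 and -2.92.

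Arterial genes were mixed in Runx1-positive cells, with list medians of -0.12 and 0.12. Igfbp3 (-1.13 and -0.82) was lower at both stages, Hey2 was higher at E9 (0.89, against 0.49 at E9.5) and Vegfc at E9.5 (0.62, against 0.52 at E9). Sox17 (-0.40 and -0.53), Efnb2 (0.015 and 0.20), Dll4 (-0.25 and -0.47), Mecom (0.22 and 0.36) and Cdkn1c (0.56 and 0.39) differed by less than 1.5-fold. The Notch pathway list had medians of -0.27 and -0.47, with Hes1 at -0.44 and -0.99, and the BMP and TGF-beta response list -0.40 and -0.28. Extracellular matrix and adhesion genes had medians of -0.33 and -0.46, with Nid2 at -1.30 and -2.06 and Fn1 the other way at 0.59 and 0.89. G1/S genes had medians of 0.15 and 0.19, with Cdca7 at 0.57 and 0.64, and G2/M genes 0.0080 and -0.042. The interferon and inflammatory list had medians of 0.19 and 0.37, with Ifitm3, of which 12.3% is shared, at 0.78 and 0.86. The fetal growth and let-7 axis list had medians of 0.17 and 0.17, and glycolysis -0.027 and -0.29. Cxcr4 stood at -0.54 (-1.89 to 0.55) and -0.82 (-3.93 to 1.15), so a difference was not detectable at this depth. With a floor of 20 CPM the hemogenic medians were 0.51 and 1.49 and the blood progenitor medians 0.44 and 1.86; with the stricter cell filter and new clusters, where cluster 4 was left out, the E9.5 medians were 0.80 and 1.08 and the E9 blood progenitor median 0.96. In that repeat the E9.5 medians of pan-endothelium (0.13), extracellular matrix and adhesion (0.24), Notch pathway (0.27) and BMP and TGF-beta response (0.27) were positive, VEGF and shear response stood at -0.057 and arterial endothelium at 1.08, while G1/S turned to -0.27. Venous genes (-0.79) and Wnt response (-1.66) stayed lower. Their E9.5 medians were also smaller with no floor on genes, at -0.51 and -1.74, and clustered again without cells over 5% haemoglobin, at -0.44 and -1.39.

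**Figure D3:**
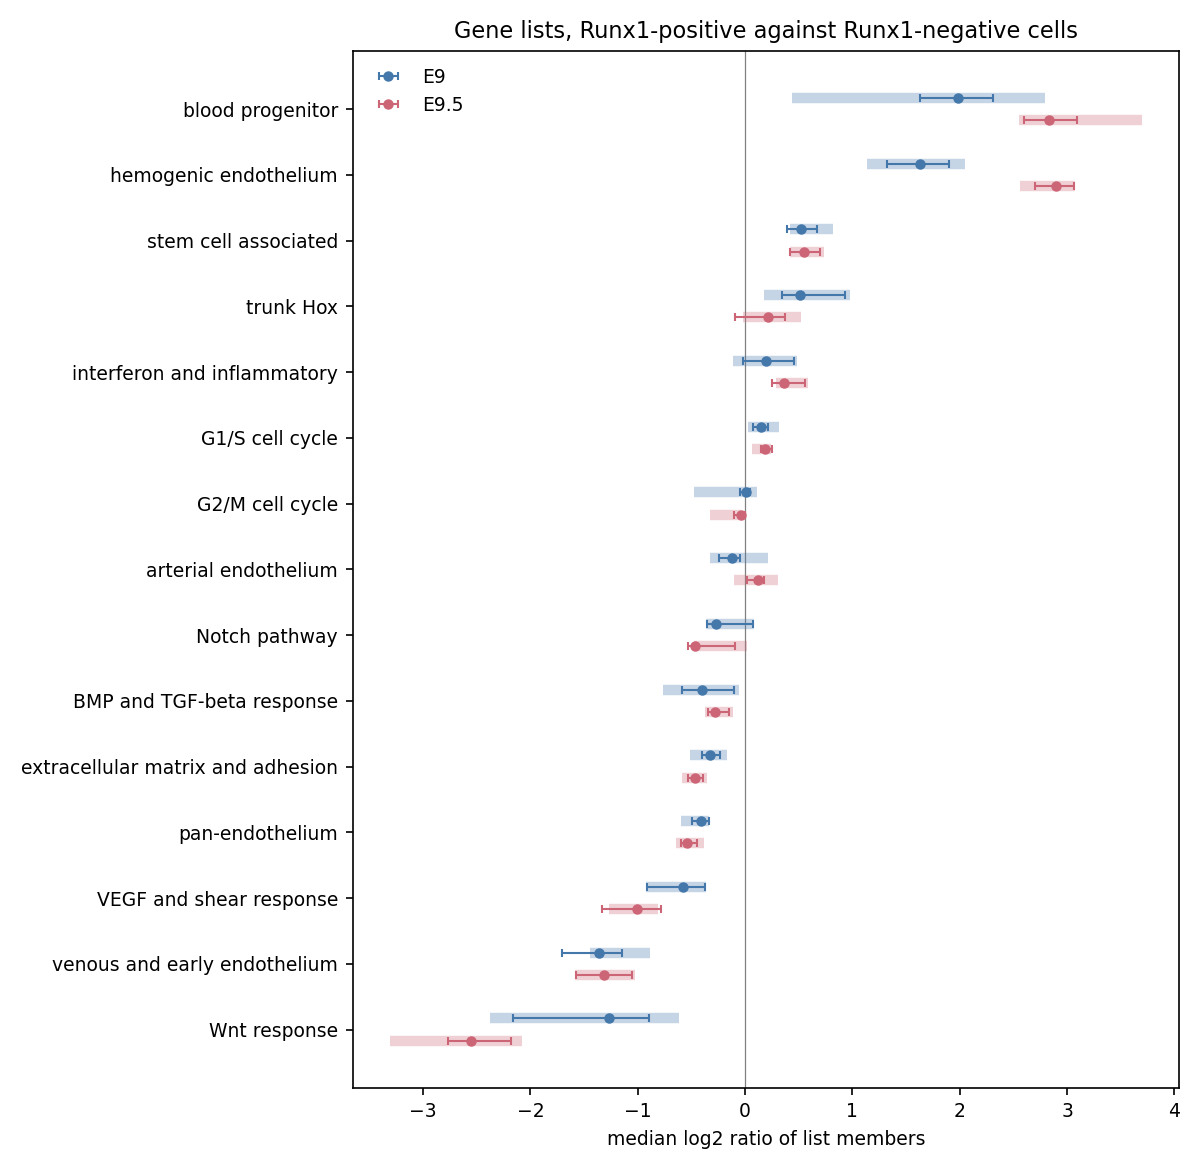
Median log2 ratio of each gene list in Runx1-positive over Runx1-negative cells at E9 and E9.5; points are medians with 95% counting intervals, and pale bars span 100 further thinning draws. Hemogenic endothelium lies at 1.63 and 2.90 and venous and early endothelium at -1.36 and -1.31.

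The study asks whether stem cells and multipotent progenitors come from separate hemogenic endothelium, and Cxcr4, a receptor on arterial endothelium, was taken as the dividing marker. With thinning, 34 of 471 endothelial and haematopoietic cells had a Cxcr4 UMI at E9 (7.22%, 5.05% to 9.94%) and 11 of 1143 at E9.5 (0.962%, 0.481% to 1.72%). In cluster 8, 0 of 57 and 0 of 73 cells had one, which allows shares of up to 5.26% and 4.11%. The E9.5 share was thus not above what the background allows. The E9 share was above it, but the lower end of its interval, 5.05%, was not. Without thinning the shares were 17.7% and 2.57%, against 6.56% and 1.14% in cluster 8. Among Runx1-positive cells, 1 of 37 had a Cxcr4 UMI at E9 (2.70%, 0.0684% to 14.2%; 15.2% without thinning) and 0 of 130 at E9.5, which allows up to 2.31% (1.05% without thinning). Among Runx1-negative cells the shares were 7.60% (5.29% to 10.5%) and 1.09% (0.543% to 1.93%). The E9 share among Runx1-positive cells ran from 0% to 16.7% over 100 further thinning draws, and whether it differed from that of negative cells was not detectable at this depth.

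After thinning, 1 and 0 Runx1-positive cells were also Cxcr4-positive, too few to split hemogenic cells by Cxcr4. On unthinned counts 10 of 66 Runx1-positive cells of E9 were Cxcr4-positive, with a median of 35200 UMIs against 36489.5, while at E9.5 there were 2. Without thinning 4 of 61 E9 cells of cluster 8 (6.56%) had a Runx1 UMI, against 13.7% of endothelial and haematopoietic cells. Some of the 66 cells, the 10 included, may thus be positive by background, which was not tested. In these 10 cells against the other 56, the arterial endothelium list had a median of 0.60 (0.37 to 0.82; 6 of 12 members higher), with Gja5 at 1.34 (1.05 to 1.62). The hemogenic endothelium list stood at -0.82 (-1.45 to -0.58; 8 of 12 lower, 2 at their bound), blood progenitor at -0.85 and stem cell associated at -0.21 (-0.51 to -0.015), with Runx1 itself at -0.80. Immediate early and dissociation stress genes were higher by a similar amount as the arterial ones, at 0.55 (0.28 to 0.91; 8 of 16 higher).

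Cxcr4-positive and negative cells were also compared over all endothelial and haematopoietic cells, a choice made after seeing the data. Cxcr4-positive cells carried more RNA of arterial genes at both stages. Venous and hemogenic genes were lower at E9. At E9.5, with 11 positive cells, their medians were also negative. Both were exactly 0 when cells were thinned to 50% of the number, the value set for members too low to measure. That setting therefore gives no direction. The arterial endothelium list, without Cxcr4, had medians of 0.92 at E9 (0.84 to 0.98; 11 of 12 members higher) and 0.89 at E9.5 (0.75 to 1.15; 11 of 13 higher), both at the 100th percentile. The connexin gene Gja5 (ENSMUSG00000057123, mm10 chromosome 3, 96904693 to 97077416) stood at 432.5 CPM against 176.7 CPM at E9 (1.29, 1.14 to 1.44) and at 541 CPM against 156.4 CPM at E9.5 (1.79, 1.52 to 2.05). Gja4 (0.92 and 1.24), Hey1, a Notch target (1.03 and 1.44), Dll4 (1.04 and 0.89), Efnb2 (0.79 and 0.89), Vegfc (1.09 and 1.01) and Nrp1 (0.93 and 0.75) were higher at both stages. The Notch pathway list had medians of 0.49 and 0.36, the VEGF and shear response list 0.59 and 0.61, and the extracellular matrix and adhesion list 0.59 and 0.40; Esm1 stood at 1.15 and 0.71, though at E9.5 a further draw reached -1.13. By the fixed rule, Cdkn1c, a cell cycle inhibitor (1.04 and 1.11), Mecom (1.06 and 1.27), Btg2 (1.20 and 1.43), Cav1 (1.51 and 1.44), Tmem100 (0.97 and 1.51), Sat1 (0.83 and 1.36), Vwf (0.96 and 1.32), Rem2 (1.32 and 1.99) and AU021092 (1.19 and 1.93) were higher. Smad6 stood at 1.12 and 0.35, and Cdh5 at 0.66 and 0.41. Unlike in the split among Runx1-positive cells, the blood progenitor medians were positive, at 0.39 (-0.41 to 0.68) and 0.93 (0.088 to 1.36; 4 of 7 higher), and so were the stem cell associated ones, at 0.20 (-0.0093 to 0.34) and 0.24 (-0.11 to 0.62). The blood progenitor median at E9 was -0.30 with no filter on cells. At E9.5 it was 0.069 on unthinned counts. It was exactly 0, the value set for members too low to measure, with no filter on cells, with the stricter filter and when thinned to 50%. The immediate early and dissociation stress list had medians of 0.25 (0.14 to 0.45) and 0.29 (0.12 to 0.62), which crossed 0 in some further draws and were 0.74 and 0.70 with no filter on cells.

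Nr2f2 had 0 counts in the Cxcr4-positive cells of both stages, which put it at least 8.22-fold lower at E9 and at least 3.33-fold lower at E9.5. Aplnr stood at -2.72 and -2.40 and Nrp2 at -1.81 and -2.58 (2 counts, -5.63 to -0.72), and the venous and early endothelium list had medians of -1.49 and -0.41 (3 of 9 members lower, 1 higher). The size of the E9 median depends on the setting: it was -0.88 over 100 further thinning draws (-2.06 to -0.17), -0.65 with no filter on cells, -0.62 with the stricter filter and -0.19 with a floor of 20 CPM. The hemogenic endothelium list had medians of -0.59, which was -0.022 with that floor, and -0.90 (3 of 11 members at their bound), with Runx1 at -1.71 (-3.34 to -0.47) at E9 and 0 counts at E9.5, at least 1.43-fold lower. The trunk Hox list had medians of -0.72 and -0.38. Sfrp2 had 1 count at E9 (-4.75, -10.06 to -2.27) and 0 at E9.5 (at least 2.29-fold lower). G2/M genes had medians of -0.65 (33 of 52 members lower) and -1.48 (40 of 52 lower), with Ccnb1 at -1.59 and -2.91, Ube2c at -1.27 and -1.84, Cdc20 at -1.27 and -2.88, Aurka at -1.25 and -2.62, Cdca8 at -1.10 and -1.51, Fam64a at -1.12 and -2.42 and Ckap2 at -2.17 at E9 and at least 2.50-fold lower at E9.5, where it had 0 counts. Cenpe stood at -1.11 and -4.11 (2 counts, -7.15 to -2.25), and Cenpf, of which 10.3% is shared, at -1.10 and -3.57 (3 counts, -5.85 to -2.02). The E9.5 median of G2/M genes was smaller elsewhere, at -0.59 with no filter on cells, -0.82 with the stricter filter and -0.70 without thinning (-1.84 to -0.35 over draws). The G1/S list stood at -0.096 and -0.36, but its direction depended on the setting: at E9 it was 0.073 with the stricter filter, and at E9.5 it was 0.056 with no filter, 0.011 with the stricter filter and 0.20 when thinned to 50%. Cell cycle inhibitors stood at 0.32 and 0.69. The G2/M median at E9 ran from -1.0 to 0.089 over 100 further thinning draws and was 0.049 with no filter on cells, so its direction at E9 depends on which cells carry the few Cxcr4 UMIs. Itgb3 stood at 4.12 at E9.5, from a single cell with 21 counts, and had 0 counts at E9, and Procr stood at 0.44 (-0.060 to 0.91) and 1.57.

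**Figure D4:**
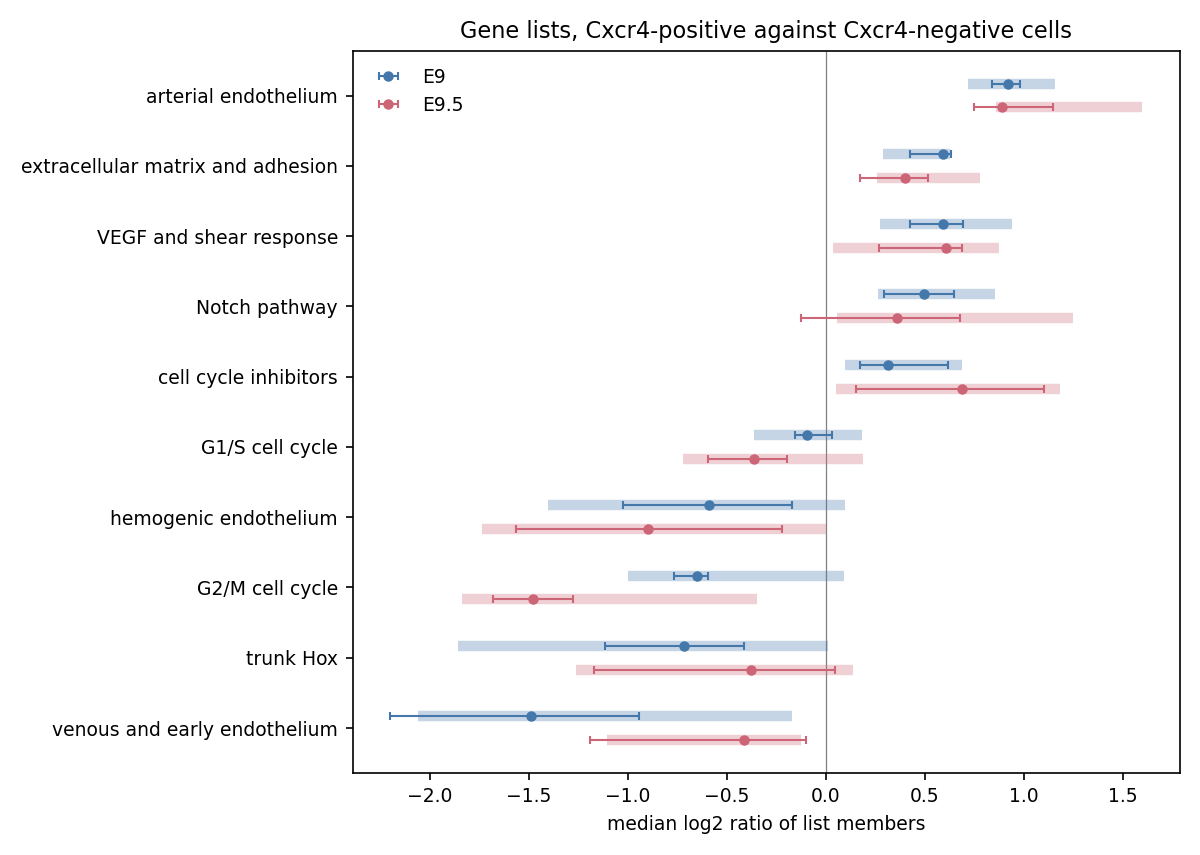
Median log2 ratio of each gene list in Cxcr4-positive over Cxcr4-negative cells at E9 (34 positive cells) and E9.5 (11 positive cells); points are medians with 95% counting intervals, and pale bars span 100 further thinning draws. Arterial endothelium lies at 0.92 and 0.89, and the draws for G2/M genes at E9 span 0.

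Comparing E9.5 with E9 within Runx1-positive cells, 130 and 37 cells, describes stage differences of cells with a Runx1 UMI. Some of them may be positive by background. At E9 7.86% of cells were positive, where cluster 8 allows up to 5.26%, and at E9.5 11.4%, against 2.74% in cluster 8. The share of background cells may thus differ between the stages and shift these medians, which was not tested. Hemogenic and blood progenitor genes were higher at E9.5 and glycolysis genes lower. The hemogenic endothelium list had a median of 1.26 (1.0 to 1.48; 8 of 12 members higher, 0 lower; 0.69 to 1.66 over draws). Gfi1 stood at 73.6 CPM and 20.3 CPM (1.86, 1.29 to 2.48), Neurl3 at 50.6 CPM and 9.45 CPM (2.42), Myb at 25.0 CPM and 6.54 CPM (1.93) and Gfi1b at 9.73 CPM and 1.45 CPM (2.74, 0.76 to 5.85), with Runx1 itself at 0.076. The blood progenitor list had a median of 1.09 (0.81 to 1.37; 9 of 11 higher), with Coro1a at 1.33, Plek at 2.74 and Ptprc at 2.16; Rac2 stood at 1.32 but ran from -0.94 to 4.42 over draws. Myeloid and lymphoid priming genes had a median of 2.30 over 5 measured members, with Prtn3 at 3.27, Mpo at 2.30 and Ikzf1 at 2.38, each from 3 counts at E9. When cells were thinned to 50% of the number, the hemogenic, blood progenitor and priming medians fell to 0.45, 0.34 and 0.90. Within cluster 4, with 8 cells of E9, the priming median was -0.039 (-0.78 to 0.80). The macrophage list stood at 3.01, with 2 of 7 members at their bound; C1qc stood at 32.8 CPM and 0.727 CPM but had a UMI in 2.31% of the E9.5 cells. Cebpb stood at 252.7 CPM and 1.45 CPM (7.44, 5.58 to 10.49), Lyz2, of which 17.7% is shared, at 65.5 CPM and 4.36 CPM (3.91), and Cd200r1 at 23.7 CPM and 0.727 CPM (5.03).

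Of stem cell associated genes, with a median of 0.054 (7 of 20 higher, 3 lower; -0.046 to 0.32 over draws), Hlf stood at 22.1 CPM and 4.36 CPM (2.34, 1.14 to 3.83), Angpt1 at 1.66 and Pdzk1ip1 at 1.91, while Mecom (-0.049), Cdkn1c (-0.35) and Kit (0.53) differed by less than 1.5-fold. Itgb3 stood at 28.9 CPM and 5.09 CPM (2.50), Procr at 0.39 and Cdh5 at -0.15. The arterial list had a median of 0.078 (-0.29 to 0.34 over draws), with Gja5 at 0.34, Efnb2 at 0.078 and Dll4 at -0.52. It was 1.38 within cluster 4 and 0.73 with the stricter cell filter and new clusters. The venous and early endothelium list stood at -0.092 (-0.69 to 0.29 over draws) and the pan-endothelium list at -0.20. The pan-endothelium median turned to 0.53 within cluster 4, 0.54 with the stricter filter and new clusters, and 0.31 clustered again without cells over 5% haemoglobin, where the venous one was 0.55. Cxcr4 had 2 counts at E9.5 and 7 at E9 (-2.97, -6.27 to -0.58). Glycolysis had a median of -0.82 (9 of 15 lower, 1 higher; -0.88 to -0.61 over draws), with the glucose transporter gene Slc2a1 at -1.12 and Slc16a3 at -2.14, and the hypoxia response list -0.55, which was 0.59 within cluster 4. The extracellular matrix and adhesion list had a median of -0.30 with Col4a1 at -1.37, but 0.51 within cluster 4 and 0.32 and 0.13 in the repeats with new clusters. The nitric oxide synthase gene Nos3 stood at -1.90 and the endothelin gene Edn1 at 1.44. The trunk Hox list had a median of 0.25, with Hoxb9 at 1.26 and Hoxb8 at -1.72. Dlk1 (-1.89), the Wnt agonist gene Rspo3 (-2.01), Mall (-2.04) and Anxa11 (-4.12) were lower, and the heat shock gene Hspa1a (3.09) and Kif2a (2.44) were higher. Genes named over all cells recurred here: Eid2 (3.92), Hist1h2ap (2.77), H1fx (2.61), Ppp1r14b (2.25), Akirin2 (2.15) and Basp1 (2.13) were higher, and Sox18 (-4.64), Gapdh (-2.51), Igfbp5 (-2.45), AY036118 (-2.26), Spag7 (-2.05) and Tuba1c (-1.86) lower; Plp2, of which 84.9% is shared, stood at -1.74. The higher hemogenic and blood progenitor medians belong to Runx1-positive cells as a whole. These lay in different clusters at the stages, and most clusters came almost entirely from 1 library. Within cluster 4, with 8 cells of E9, the medians were -0.39 and -0.82. They were -0.33 and -0.60 with the stricter cell filter and new clusters, where the E9.5 cells of cluster 4 were left out.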

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

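The tests in this part were chosen after the results were seen, except the test of Cxcr4 within cells with a Gja5 UMI, whose prediction came before. Results were picked out here because Runx1-positive cells stood above Runx1-negative cells at 1 stage and below them at the other; none of these differences between stages was tested, since each stage is 1 library. Lyve1 stood at -1.98 at E9 and 1.41 at E9.5, a difference of 3.39, and kept both directions in all 100 further thinning draws. It was the leading gene of cluster 10, with 17 cells of E9 and 0 of E9.5, and 0 of its 16 thinned cells were Runx1-positive. The Runx1-negative cells of E9 thus included Lyve1-rich cells that the E9.5 library lacked, and the comparison without them was not made. Cyp26b1, which encodes an enzyme that breaks down retinoic acid, stood at -1.67 and 0.49, a difference of 2.15. Hspa1a stood at -1.46 and 1.29, a difference of 2.75, and its E9 value reached 0.10 in a further draw. Gja5 stood at -0.38 and 0.29, a difference of 0.67, with E9 draws from -0.76 to 0.25. Hbb-y stood at 2.25 and -2.57, a difference of -4.82, and draws crossed 0 at both stages. Without the 3 E9.5 cells over 5% haemoglobin the E9.5 value was 0.98 (0.77 to 1.19), so the opposite direction rests on those cells. The arterial endothelium list stood at -0.12 and 0.12, a difference of 0.25, and draws crossed 0 at both stages.

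Cxcr4 stood at a log2 ratio of -2.61 at E9.5 against E9 over all kept cells. This ratio is of CPM, which is scaled to the summed total, so fewer UMIs per cell at E9.5 would not by itself lower it. Shares of positive cells do depend on depth. After thinning, the E9 share of Cxcr4-positive cells was still 7.50 times the E9.5 share (3.71 to 16.4), which argues against depth as the cause of the difference in shares. The tables also argue against fewer cells with the arterial gene Gja5 at an unchanged level within them. At E9 55.2% of cells had a Gja5 UMI and at E9.5 40.1%, and within these 260 and 458 cells Cxcr4 stood at -1.88 (-2.52 to -1.28). A difference between the libraries that all cells share stays open, since cluster 8 gave -1.86 with an interval from -7.48 to 1.48 on 4 and 1 counts. A developmental difference between the stages may equally account for it, and with 1 library per stage the library and the stage cannot be told apart.

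Single genes such as Cebpb, Eid2, Basp1, Sox18 and Gapdh differed between the stages by large factors. For most of the 17 genes above the background of cluster 8, the tables argue against a change within endothelial cells only. For 16 of them the log2 ratio there was over 0.5 times that in endothelial and haematopoietic cells. The median was 0.943 times, with 0.871 to 1.10 when these genes were resampled. That median cannot speak for all 24 genes. The filter asked for a high level in cluster 8 at the stage with more, which a gene changed in endothelial cells only tends to fail. The explanation stays open for Igfbp5, at 0.135 times, and for the other 7 of the 24, including Sox18 and Cebpb. Those 7 reached at most 29.1% of their endothelial level there, within 2 times the highest share of a pan-endothelial gene. Transcript ends shared with other genes are not the whole cause, since 5 of the 24 genes (20.8%) share 10% or more of theirs, nor is a trend with GC content, since the median size of the ratios was 2.14 before and 2.17 after its removal. A candidate explanation is a difference in handling, library preparation or sequencing that reached all cells, and a stage difference shared by all cell types is the biological one. With 1 library per stage these cannot be told apart.

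Haemoglobin RNA was higher at E9.5, with a log2 ratio of summed counts of 5.91. The tables argue against a few haemoglobin-rich cells as the whole cause: the 3 cells with over 5% haemoglobin held 93.0% of the E9.5 haemoglobin counts, and without them the ratio was 2.07 (1.88 to 2.26; 1903 and 264 counts). Whether it was free RNA from 1 source could not be decided. The share of Hbb-bh1 among Hbb-bh1 and Hbb-y counts spanned 26.2 percentage points, from 13.8% in cluster 2 (up to 19.5%) to 40.0% in cluster 8 (from 24.9%). Cluster 8 held only 16 and 24 of these counts. Clusters 2, 3, 4 and 5 lay at 13.8% to 17.7% with overlapping intervals, and cluster 1 at 27.0% (22.6% to 31.6%). The intervals take every UMI as independent, so a few cells under the 5% limit could set a cluster's share. Free RNA from 1 or several sources, red cells attached to sorted cells and a difference between the stages stay open as possible explanations.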

How the results depend on the processing

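Alternatives added after the data were seen were the GC correction, genes without shared ends, removal of cells with haemoglobin, macrophage or platelet RNA, new clusters under other filters, further thinning draws, and the Cxcr4 split over all endothelial and haematopoietic cells. No paired analysis was possible because both samples carry replicate number 1 and each stage has 1 library; leaving out a replicate was not possible either. Of values for single genes, 3345 stayed within the interval of the main value, 702 lay outside it, and 32 called higher or lower changed direction. Of list medians outside the main results 1225 stayed, 276 moved and 6 turned. Of the main list medians 86 stayed, 16 moved and 3 turned, of the main Runx1 and Cxcr4 shares 38 stayed and 12 moved, and of the shares of hemogenic clusters 16 stayed and 4 moved. The hemogenic median over all cells lay between 0.18 and 0.87 under all alternatives tried, and the arterial median of Cxcr4-positive cells at E9 between 0.82 and 1.06. Depth limits the Cxcr4 results, with 34 and 11 positive cells. Unless stated, the cause was not tested.

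With clusters named hemogenic in place of Runx1-positive cells, which leaves 8 cells of E9, the shares were 1.70% and 15.3%, the Cxcr4 share within them at E9 0%, and the stem cell associated medians 0.29 and 0.70. Between stages within them the hemogenic median was -0.39, blood progenitor -0.82 and myeloid and lymphoid priming -0.039, with Angpt1 at -0.078, Coro1a -1.03, Gfi1b -1.29, Hoxb8 0.21, Hspa1a -0.037, Igfbp5 0.67, Ikzf1 -0.078, Mall 0.12, Myb -0.42, Ptprc -0.61, Rac2 -2.40, Rspo3 0.67 and Slc2a1 0.69. Against the other cells at E9, Hbb-y stood at -1.23, Hey2 -0.34, Hoxa5 -0.23 and Hspa1a 1.69. The E9 medians against the other cells turned to -0.36 for trunk Hox and for the fetal growth and let-7 axis, and arterial endothelium fell to -1.47. These are other cells, since most Runx1-positive cells of E9 lay in cluster 7.

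With no filter on cells, whose thinning number and draw differ, Cxcr4-positive cells of E9 had an arterial median of 0.82 and a G2/M median of 0.049, with Cdc20 at 0.000503, Cenpe 0.077, Cenpf 0.10 and Ube2c 0.11; Rem2 at E9.5 stood at -0.12. For Runx1-positive cells the stem cell associated median at E9 was 0.71 and Hbb-y at E9.5 was 2.77. With at least 3000 genes and at most 5% mitochondrial counts the E9 stem cell associated median was 0.67, the E9 Cxcr4 share among Runx1-positive cells 0%, Itgb3 in Cxcr4-positive cells of E9.5 -0.032 and Rac2 within Runx1-positive cells -0.15. Thinned to 50% of the number, which lowers shares by construction, Runx1 shares were 4.37% and 7.05% and the E9 Cxcr4 share among them 0%; the hemogenic median within Runx1-positive cells was 0.45, with Rac2 at -1.0, and AU021092 in Cxcr4-positive cells of E9 stood at -0.15, Hspa1a in Runx1-positive cells of E9 at 0.40 and Hbb-y at E9.5 at 3.22. Unthinned, Runx1 shares were 13.7% and 15.9%, the E9 Cxcr4 share among them 15.2% and Hbb-y at E9.5 1.77. Without cells over 5% haemoglobin Hbb-y at E9.5 was 0.98. Without cells with macrophage or platelet RNA Fcgr3 at E9 was -0.013 and the blood progenitor median of Cxcr4-positive cells of E9.5 -0.065.

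The arterial stage median over all cells was 0.17 with cells weighted equally, -0.043 with a floor of 20 CPM or without members of other lists, and -0.036 after the GC correction. With that floor the hemogenic stage median was 0.18 and the E9 stem cell associated median of Runx1-positive cells 0.39; with no floor that of E9.5 was 0.82. The E9 arterial median of Cxcr4-positive cells was 1.06 with at least 2 UMIs and 1.05 over all kept cells. The share of hemogenic-named clusters at E9.5 was 11.1% at resolution 1.0, and without cell cycle genes 0.554% and 10.3%. Clustered again after the stricter filter, the cluster with 179 of the 188 cells of cluster 4 was also named macrophage and left out, which gave an E9.5 Runx1 share of 2.46%, hemogenic and blood progenitor medians within Runx1-positive cells of -0.33 and -0.60, and an E9 stem cell associated median of 0.68. Clustered again without cells over 5% haemoglobin, a cluster with 141 of them was named hematopoietic progenitor and macrophage. This gave 4.15%, -0.43 and -0.63. The share of hemogenic-named clusters at E9.5 was then 10.3%, because clusters named hematopoietic progenitor count in that share.

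No value was had for the Cxcr4 split at E9.5 with at least 2 UMIs, which left too few cells, for the thinned split among Runx1-positive cells (the unthinned one, 10 against 56 cells of E9, gave an arterial median of 0.60 and a hemogenic one of -0.82), and for lists left with too few members, mainly macrophage, epithelium, and myeloid and lymphoid priming under a floor of 20 CPM or new clusters.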

Other observations

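The results in this part were picked after their values were seen. Of trunk Hox genes, Hoxa10 and Hoxa9 were higher at E9.5 over all kept cells and Hoxb8 and Hoxb5 lower. Hoxa10 stood at 8.04 CPM at E9.5 and 3.05 CPM at E9 (log2 1.40, 0.98 to 1.84) and Hoxa9 at 40.0 CPM and 21.4 CPM (0.91, 0.74 to 1.07). Hoxb8 stood at 21.3 CPM and 39.4 CPM (-0.89, -1.04 to -0.74) and Hoxb5 at 20.3 CPM and 34.6 CPM (-0.77, -0.93 to -0.61). The directions were the same in endothelial and haematopoietic cells alone, with Hoxa10 at 1.70, Hoxa9 at 1.10, Hoxb8 at -0.84 and Hoxb5 at -0.81. In cluster 8 Hoxa9 stood at -0.31 (-0.81 to 0.19). The trunk Hox list as a whole had a median of 0.13 (85.3rd percentile; 3 of 15 measured members higher and 2 lower), which was 0.44 in endothelial and haematopoietic cells, 0.54 with a floor of 20 CPM and -0.090 without members that are in another list.

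Genes of the retinoic acid pathway were also mixed, with a list median of -0.20 (1.06th percentile). Stra6, a retinol transporter gene, stood at 8.75 CPM at E9.5 and 2.89 CPM at E9 (1.60). Cyp26a1, which encodes an enzyme that breaks down retinoic acid, stood at 33.8 CPM and 72.3 CPM (-1.10), and Aldh1a2, which encodes the enzyme that makes it, at 3.82 CPM and 11.7 CPM (-1.62). In endothelial and haematopoietic cells alone Stra6 stood at 2.92, Cyp26a1 at -1.17 and Aldh1a2 at -0.50; Aldh1a2 was among the leading genes of cluster 8. Within Runx1-positive cells Lin28a, an RNA-binding protein gene of early embryonic cells, stood at 14.9 CPM at E9.5 and 42.2 CPM at E9 (-1.50, -2.09 to -0.91).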
